A study of Mus musculus with 6 samples.

How the data were processed

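RNA was prepared from microdissected cochlear lateral wall, and its size profile was checked on a Bioanalyzer, per the labels' protocols. Biotin-labelled cRNA was made with the Affymetrix 3′ IVT Express kit, per the labels' protocols. Such a kit primes from the poly(A) tail, so signals come mainly from 3′ ends, and 1 sample is hybridised per array. The submitters' processing notes name Affymetrix Expression Console, RMA and MAS5, with versions and roles not given in the sources used here. Probe intensities and scanner files were not used here, so background correction, signal over background and scan batches were not examined. The deposited table holds log2 values with 2 decimals for 45101 probe sets on 6 arrays, ranging from 2.66 to 14.76, per its values. RMA brings arrays to a shared distribution, and the array medians of the deposited log2 values were 6.26 to 6.30. A shift of most genes in one direction would be removed by such scaling. The number of arrays, 3 per age, limits the precision of every value.

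Groups were taken from the labels, with 3 young samples and 3 old samples. The 64 control probe sets were left out of the tests, which leaves 45037. Gene names came from GEO's platform annotation of the array, in which 34945 probe sets had 1 symbol, 932 had several and 9160 were not listed. Symbols were compared with current RefSeq symbols through Entrez identifiers, and 0 were updated. No gene was named from a probe set with several symbols. A gene was represented by its brightest probe set over all 6 arrays, which gave 18193 genes, and 9010 of them had more than 1 probe set.

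The deposited log2 values were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without intensity trend or robust variance), with age as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets. The adjusted p printed for a gene is that of its probe set among all 45037. The gene count was adjusted again over 18193 genes. The 42 gene lists were fixed before the data were examined, and 957 of their 1071 different genes were measured. They were tested with camera at a preset correlation of 0.01 between genes, over lists with at least 5 measured genes, and p-values were adjusted over the 42 lists. Camera asks whether a list moved relative to the other genes. With a correlation estimated for each list, 0 of the 42 lists passed an adjusted p of 0.05, and 6 had an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move one way on balance without comparing them to others, called 11 lists. Within each list, limma p-values were also adjusted over the list alone.

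The rule for named genes was fixed before the data were examined. It takes the 12 highest and the 12 lowest differences among called genes whose brighter group lies above the median signal of all probe sets, 6.28, and whose groups do not overlap. It adds up to 4 called members per list, with 2 in each direction where both occur, or up to 2 with the smallest p where none was called. It adds 8 lateral wall genes whatever their result. Genes for other questions are named with the statement that they were chosen after their values were seen.

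The scripts were tested on simulated data. In 20 draws of arrays with the real means and spread, 200 of 45037 probe sets were changed per draw. For old against young, limma called 30.7% of changes of 0.5 log2, 80.5% of changes of 1 and 98.3% of changes of 2, and 3.50% of its calls were false. A list shifted by 0.3 log2 was found by camera in 20 of 20 draws over 18193 genes, and 10 of 820 tests of other lists were called. The simulated genes were independent, so this does not test the effect of correlated genes. Fewer probe sets were changed than the 2119 called in the real comparison. The adjustment depends on how many change, so these shares do not give the power of the real comparison.

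Alternatives fixed before the data were examined were quantile normalization again, median centring, cyclic loess, a filter on dim probe sets, an intensity trend with robust variance, array weights, the replicate number as a block, an adjusted p of 0.01, the mean of a gene's probe sets, other list tests, and leaving out each array. Of these, the setting without young replicate 2 was singled out after its Xist value was seen, and nothing else was added. Figures were drawn with matplotlib.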

Results

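Cochlear lateral wall tissue, the outer wall of the cochlear duct that holds the stria vascularis and the spiral ligament, was compared between young adult CBA/CaJ mice of 1 to 3 months and old mice of 1.5 years. Messenger RNA was profiled on 1-colour Affymetrix arrays, with 3 arrays per age and mice of both sexes. The labels present the series as the mRNA part of a study of microRNAs and aging in this tissue. The question of the comparison was which transcripts differ between the ages. Values are log2 signals, and all differences are old minus young. A mean is given ± SD with n = 3 arrays, and a difference is given ± its standard error from limma. The labels do not say whether the 3 samples of an age came from separate animals or pools, so the p-values measure the spread among these samples.

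Samples from old mice had less RNA for 17 of 27 immediate early and glucocorticoid-induced genes, 10 of 32 collagen genes, 6 of 15 bone genes and 10 of 17 marrow myeloid genes. They had more RNA for 8 of 24 macrophage genes and for the B cell-attracting chemokine Cxcl13. Camera called these lists at a preset correlation, and with an estimated correlation 0 of 42 lists passed. Groupings of the arrays into 3 and 3 that mixed the ages also gave 2 to 15 called lists at the preset correlation. Such groupings keep part of an age difference, so they do not show how many calls arise without it. Cxcl13 rose from 5.55 ± 0.10 to 8.12 ± 0.30 (limma adjusted p = 0.000442). Fos, an immediate early transcription factor, fell from 10.33 ± 0.45 to 7.52 ± 0.21 (limma adjusted p = 0.000985), and Col1a2, a chain of type I collagen, fell from 11.78 ± 0.43 to 9.09 ± 0.56 (limma adjusted p = 0.00303). In contrast, Kcnj10, the potassium channel of strial intermediate cells, was at 12.78 ± 0.13 in young and 12.76 ± 0.03 in old tissue (limma adjusted p = 0.932).

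Of 45037 probe sets tested with limma, 2119 passed an adjusted p of 0.05, 838 higher and 1281 lower in old tissue. At 1 probe set per gene, 885 of 18193 genes passed, 454 higher and 431 lower. A change of at least 2-fold was seen for 337 of the called probe sets, 77 higher and 260 lower. For all 2119 called probe sets, the 3 old values lay entirely above or entirely below the 3 young values. Over all probe sets, 23.8% had non-overlapping groups, where chance gives 10%. The counts depended on single arrays. The number of called probe sets was 985 without young replicate 1, 3393 without young replicate 2, 618 without young replicate 3, 934 without old replicate 1, 1122 without old replicate 2 and 515 without old replicate 3. The number of called genes was 399, 1635, 278, 384, 340 and 247 in the same order.

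The arrays separated by age along the first principal component, which held 52.2% of the variance. Young arrays had scores of -38.6, -11.6 and -28.0, and old arrays had scores of 27.8, 24.0 and 26.3. Array medians lay between 6.26 and 6.30. Young replicate 2 stood nearest to the old arrays on this component. Its correlation across probe sets was highest with young replicate 3, at 0.996, and was 0.994 with young replicate 1 and 0.993 to 0.995 with the old arrays. The same array had a signal of 6.06 for Xist, the RNA of the inactive X chromosome, where the other 5 arrays had 11.95 to 12.65. The Y-linked genes Eif2s3y, Kdm5d and Uty had signals on every array and were brightest in young replicate 2, at 10.46, 8.96 and 8.99. Signals of both Xist and Y-linked genes on the other 5 arrays point to samples with RNA of both sexes, hence of more than 1 animal. Young replicate 2 had the pattern of males alone, so its sex make-up differed from that of the other young samples. Signal over background was not examined for these probe sets. Xist and these genes were singled out after their values were seen. Without this array, a planned setting that was singled out after its Xist value was seen, 1851 probe sets were called higher and 1542 lower. The control probe sets for the 3′ end exceeded those for the 5′ end of Gapdh by 1.18 ± 0.10 in young and 1.36 ± 0.10 in old arrays, and of Actb by 1.53 ± 0.07 and 1.67 ± 0.24. The exact 2-sided permutation p was 0.1 for Gapdh, the smallest that 3 against 3 can give, and 0.4 for Actb.

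Most measured immediate early genes, which are transcribed within minutes of a stimulus, and genes induced by glucocorticoids fell in old tissue. Of 27 measured members of this list, 17 fell, 0 rose and 10 did not pass (1 rising and 20 falling when adjusted over the list alone). The median difference was -1.04 (camera adjusted p = 6.50e-22, and adjusted p = 0.255 with an estimated correlation). Egr3 fell from 8.52 ± 0.77 to 4.81 ± 0.94 and Egr1 from 11.64 ± 0.71 to 8.93 ± 0.36 (limma adjusted p = 0.00614 and 0.00457). Fos and Fosl2, subunits of the AP-1 factor, had differences of -2.81 ± 0.21 and -2.39 ± 0.20 (limma adjusted p = 0.000985 and 0.00144). Fkbp5, a co-chaperone of the glucocorticoid receptor and one of its targets, fell from 10.77 ± 0.13 to 8.61 ± 0.14 (limma adjusted p = 0.000170). Further genes with differences among the lowest were Maff (-2.60 ± 0.24), the orphan nuclear receptors Nr4a1 (-2.34 ± 0.17) and Nr4a3 (-2.16 ± 0.15), and Arrdc2 (-2.21 ± 0.17). The limma adjusted p were 0.00194, 0.000985, 0.000965 and 0.00110. Fkbp5 and Nr4a3 each had 2 other probe sets, with young means of 6.09 and 3.07 and of 6.25 and 3.99, that did not pass. The 3′ excess of the Gapdh control probe sets was 1.07 to 1.25 in young and 1.26 to 1.45 in old arrays, so it was higher on every old array than on any young one, and that of Actb overlapped. Averaged over a gene's probe sets, the difference was -1.81 for Egr3, -1.18 for Fosl2, -0.75 for Fkbp5 and -0.74 for Nr4a3, past the threshold.

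**Figure D1:**
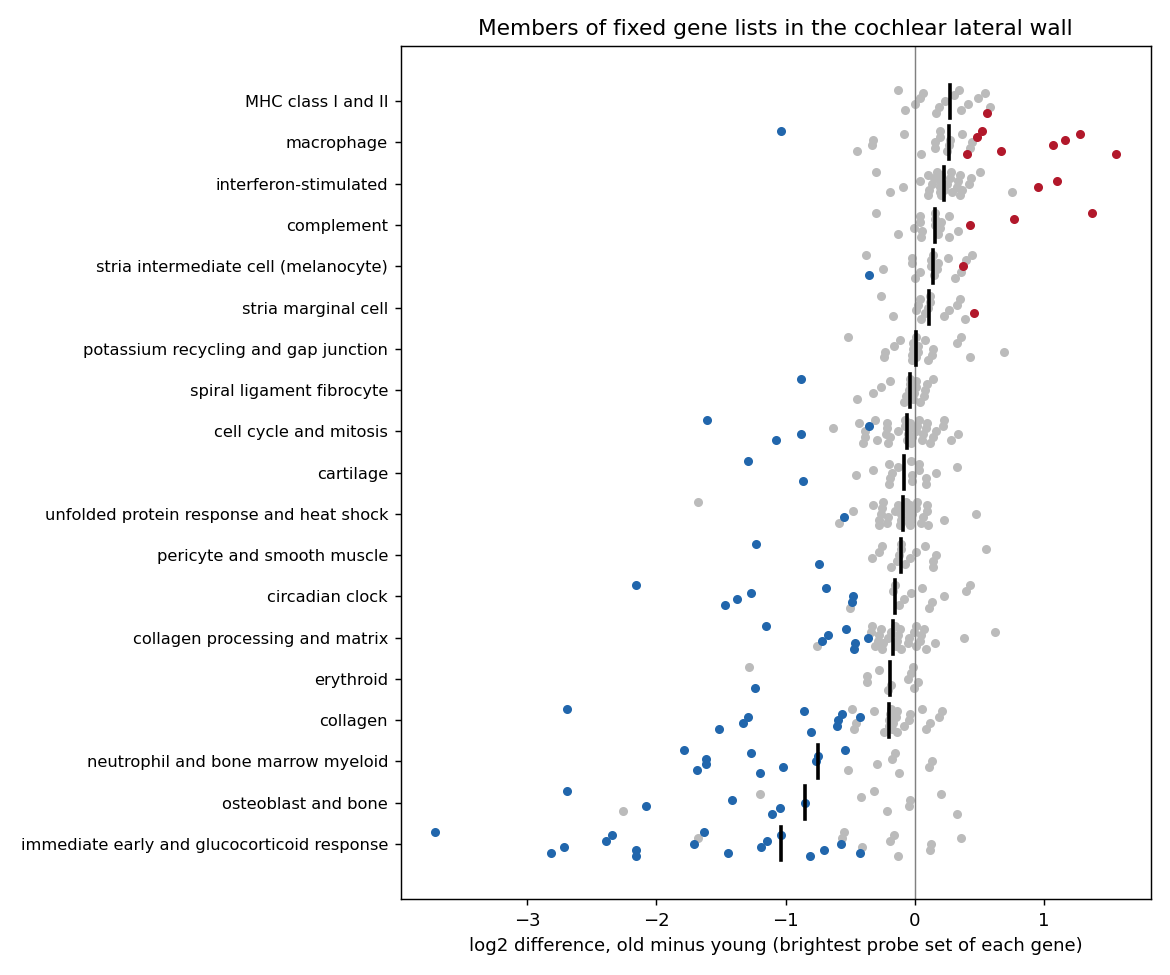
Log2 difference, old minus young, of each measured member (points) of the 15 fixed lists past the camera threshold and of 4 lateral wall lists, with the list median as a black bar. Red points rose and blue points fell past the limma threshold, grey points did not pass; immediate early and glucocorticoid response genes had the lowest median, -1.04, and MHC genes the highest, 0.27.

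Several clock and stress genes were lower as well. Of 19 measured circadian clock genes, 7 fell and 0 rose (0 rising and 8 falling when adjusted over the list alone). The clock median was -0.16 (camera adjusted p = 0.000253, and adjusted p = 0.255 with an estimated correlation). Per1, a clock repressor that is also in the immediate early list, fell from 11.33 ± 0.52 to 9.17 ± 0.32 (limma adjusted p = 0.00423). Ciart, Nr1d1 and Nfil3 had differences of -1.47 ± 0.18, -1.38 ± 0.31 and -1.27 ± 0.16 (limma adjusted p = 0.00519, 0.0441 and 0.00548). The metallothioneins Mt2 and Mt1, small metal-binding proteins, fell from 13.54 ± 0.08 to 12.03 ± 0.17 and from 13.71 ± 0.12 to 12.86 ± 0.10 (limma adjusted p = 0.000927 and 0.00319). They were the only members of the antioxidant defence list to pass, out of 37 (0 rising and 3 falling when adjusted over the list alone, camera adjusted p = 0.694). In the senescence and DNA damage list, Gadd45b (-1.55 ± 0.25) and Btg2 (-1.48 ± 0.26) were among 4 that fell, and Gadd45a (0.59 ± 0.10) was the 1 that rose, of 25 measured (limma adjusted p = 0.0152, 0.0181 and 0.0179). That list had 2 rising and 4 falling when adjusted over the list alone and did not pass as a whole (camera adjusted p = 0.235). Of 35 genes for the unfolded protein response and heat shock, Ddit3 fell by 0.55 (limma adjusted p = 0.0303), 0 rose and 34 did not pass (1 rising and 3 falling when adjusted over the list alone). The list median was -0.09 (camera adjusted p = 0.00150, and adjusted p = 0.306 with an estimated correlation), and fry gave an adjusted p of 0.0833. The clock median was -0.09 with array weights and -0.10 without young replicate 2. With 1 array left out, the limma adjusted p exceeded 0.05 for Nr1d1 (on leaving out any array except young 2, up to 0.128), Gadd45b (without young 1 or young 3 or old 1, up to 0.0625) and Btg2 (without young 3 or old 1 or old 3, up to 0.0889). Leaving out single arrays raised the limma adjusted p above 0.05 for Gadd45a (on leaving out any array except young 2, up to 0.0867) and Ddit3 (on leaving out any array except young 2 and old 1, up to 0.114). With the mean of a gene's probe sets, the difference was -1.54 for Mt1 and -0.96 for Gadd45b, past the threshold. It was -0.32 for Ddit3 (adjusted p = 0.160), which did not pass.

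**Figure D2:**
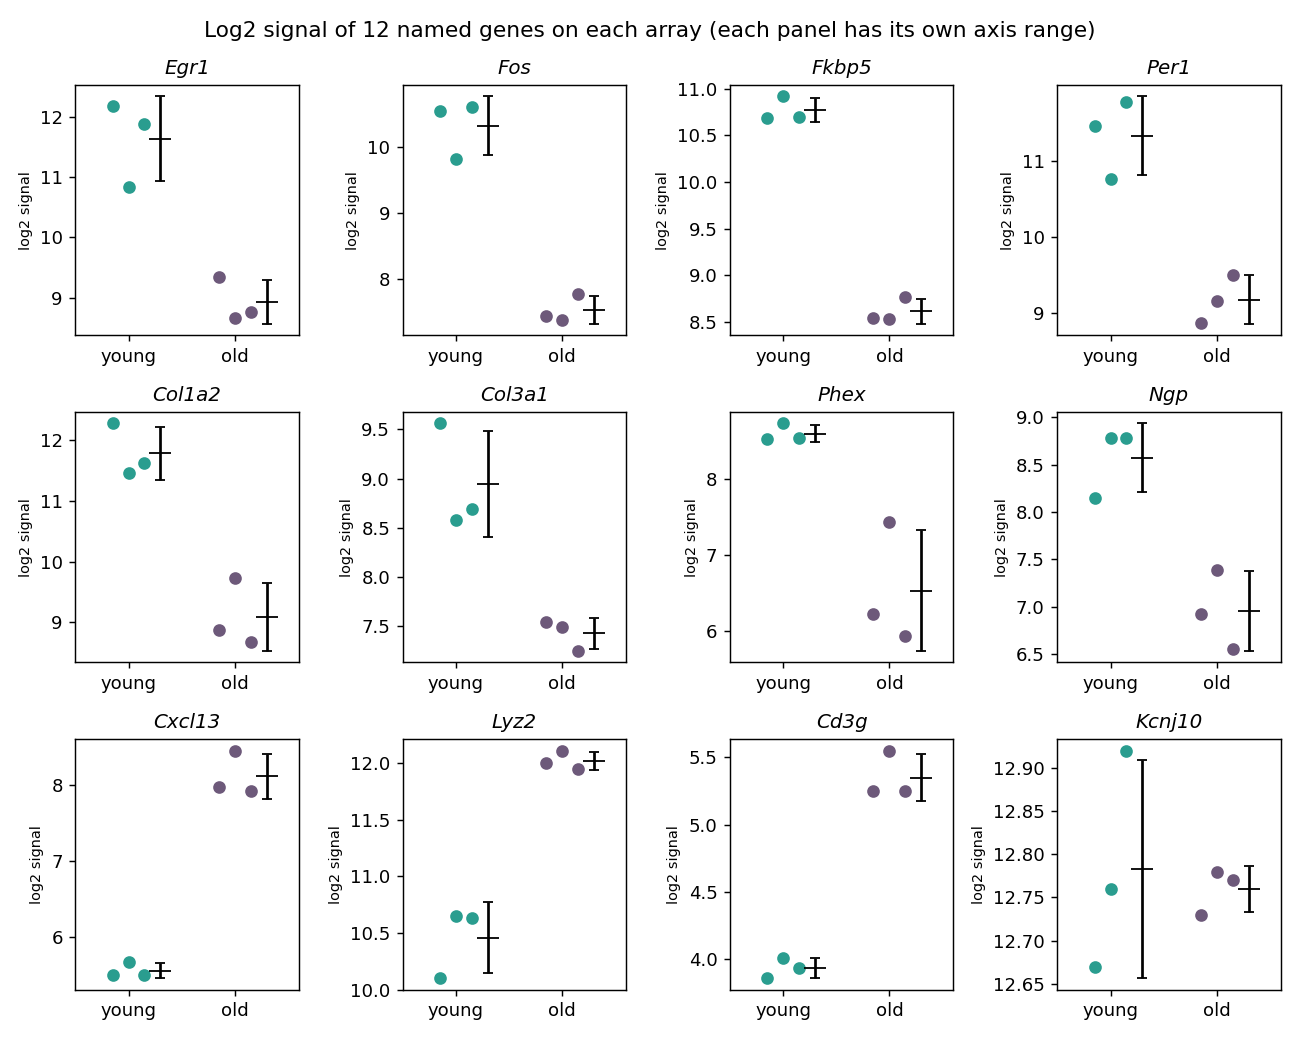
Log2 signal of 12 genes on the 3 young and the 3 old arrays (points), with the mean and SD of each age (bars, n = 3); each panel has its own axis range. Old values lay below all young values for Egr1, Fos, Fkbp5, Per1, Col1a2, Col3a1, Phex and Ngp and above them for Cxcl13, Lyz2 and Cd3g, and the ages overlapped for Kcnj10.

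Several collagens and the cross-linking enzymes Lox and Loxl1 were lower in old tissue. Of 32 measured collagen genes, 10 fell and 0 rose (0 rising and 12 falling when adjusted over the list alone). The collagen median was -0.20 (camera adjusted p = 2.86e-10, and adjusted p = 0.306 with an estimated correlation). Col1a2 had the lowest difference, -2.69 ± 0.29, followed by Col3a1 of type III collagen (-1.51 ± 0.23), Col5a2 (-1.33 ± 0.13) and Col11a1 (-1.29 ± 0.10). Limma gave adjusted p of 0.00303, 0.0117, 0.00230 and 0.000990. Of 36 genes for collagen processing and matrix, 7 fell and 0 rose (1 rising and 11 falling when adjusted over the list alone). The processing and matrix median was -0.17 (camera adjusted p = 5.79e-08, and adjusted p = 0.255 with an estimated correlation). Lox and Loxl1, which cross-link collagen and elastin, had differences of -1.15 ± 0.15 and -0.72 ± 0.09 (limma adjusted p = 0.00591 and 0.00610), and Loxl3 and Loxl4 did not pass, at -0.27 and 0.16. Col1a1 did not pass, at -0.31 (limma adjusted p = 0.511). The bone list, of which Col1a1 and Col1a2 are also members, had a median of -0.85. The collagen median was -0.37 over probe sets above the median signal and -0.30 without young replicate 2. The processing and matrix median was -0.10 with the mean of a gene's probe sets. The small proteoglycans Aspn and Ogn had differences of -0.67 ± 0.10 and -0.53 ± 0.09 (limma adjusted p = 0.0108 and 0.0169). Of 18 cartilage genes, Col11a1 and Acan (-0.86 ± 0.18, limma adjusted p = 0.0371) fell and 0 rose (0 rising and 2 falling when adjusted over the list alone). The cartilage median was -0.08 (camera adjusted p = 0.0150, and adjusted p = 0.504 with an estimated correlation), and the adjusted p was 0.0606 by camera without young replicate 1 and 0.0879 by fry. That median was -0.19 over probe sets above the median signal and -0.15 without young replicate 2. Among 26 matrix degradation genes, 4 fell, including Timp4 (-1.33 ± 0.13) and Adamts5 (-0.85 ± 0.17), and the macrophage elastase Mmp12 rose by 2.27 (limma adjusted p = 0.00230, 0.0284 and 0.00884). That list had 1 rising and 5 falling when adjusted over the list alone (camera adjusted p = 0.0626). Its camera adjusted p was 0.0105 without old replicate 2 and 0.0115 with the mean of a gene's probe sets, with medians of -0.04 and -0.06 against -0.02. In fits without 1 array, the limma adjusted p rose above 0.05 for Col3a1 (without old 3, up to 0.0566), Aspn (without young 3 or old 3, up to 0.0545) and Ogn (without young 1 or old 1 or old 3, up to 0.0899). Calls lost on leaving out 1 array, with a limma adjusted p above 0.05, were those of Acan (on leaving out any array except young 2, up to 0.142) and Adamts5 (on leaving out any array except old 2, up to 0.102). For the mean of all probe sets of a gene, the difference was -0.38 for Adamts5 (adjusted p = 0.0566), which did not pass.

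Several genes of bone and bone marrow, tissues that adjoin the lateral wall in the ear capsule, were lower in old samples. Of 15 measured osteoblast and bone genes, 6 fell and 0 rose (0 rising and 8 falling when adjusted over the list alone). The bone median was -0.85 (camera adjusted p = 2.96e-08, and adjusted p = 0.255 with an estimated correlation). Phex, which regulates phosphate handling in bone, fell from 8.61 ± 0.12 to 6.53 ± 0.80 (limma adjusted p = 0.0130). The osteocyte matrix proteins Mepe and Dmp1 fell from 8.34 ± 0.51 to 6.93 ± 0.37 and from 12.25 ± 0.12 to 11.14 ± 0.17 (limma adjusted p = 0.0232 and 0.00239). Of 17 neutrophil and marrow myeloid genes, 10 fell and 0 rose (0 rising and 11 falling when adjusted over the list alone). The marrow myeloid median was -0.75 (camera adjusted p = 1.05e-10, and adjusted p = 0.255 with an estimated correlation). The granule genes Ngp and Camp fell from 8.57 ± 0.36 to 6.95 ± 0.42 and from 8.04 ± 0.41 to 6.36 ± 0.45 (limma adjusted p = 0.00908 and 0.0102). The calprotectin subunits S100a8 and S100a9 had differences of -1.78 ± 0.36 and -1.62 ± 0.32 (limma adjusted p = 0.0304 and 0.0303). Of 12 erythroid genes, the anion exchanger Slc4a1 fell by 1.23 (limma adjusted p = 0.0219) and 0 rose (0 rising and 2 falling when adjusted over the list alone). The erythroid median was -0.20 (camera adjusted p = 0.00165, and adjusted p = 0.506 with an estimated correlation), and fry gave an adjusted p of 0.163. That median was -0.30 without young replicate 2 and -0.11 without young replicate 3. The bone median was -0.41 with the mean of a gene's probe sets, and the marrow myeloid median was -1.44 over probe sets above the median signal. Of 12 osteoclast genes, Atp6v0d2 (1.73 ± 0.19), a proton pump subunit, and Acp5 (0.90 ± 0.17), the tartrate-resistant phosphatase, rose (limma adjusted p = 0.00303 and 0.0232). The osteoclast list had 2 rising and 1 falling when adjusted over the list alone and did not pass (camera adjusted p = 0.932). With 1 array left out, the limma adjusted p exceeded 0.05 for Phex (without young 3, up to 0.0658), Mepe (without young 3 or old 1 or old 3, up to 0.105) and Ngp (without young 3, up to 0.0544). Leaving out single arrays raised the limma adjusted p above 0.05 for Camp (without young 3, up to 0.0545), S100a8 (on leaving out any array except young 1 and old 2, up to 0.128) and S100a9 (on leaving out any array except old 2, up to 0.128). In fits without 1 array, the limma adjusted p rose above 0.05 for Slc4a1 (on leaving out any array except young 2, up to 0.0914) and Acp5 (without young 3 or old 1 or old 3, up to 0.0812). Averaged over a gene's probe sets, the difference was -1.10 for Phex, past the threshold.

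Several macrophage genes were higher in old tissue. Of 24 measured members, 8 rose, 1 fell and 15 did not pass (11 rising and 3 falling when adjusted over the list alone). The macrophage median was 0.27 (camera adjusted p = 0.000135, and adjusted p = 0.415 with an estimated correlation), and 0.17 without young replicate 1. Mrc1, Cd163 and Lyve1 did not pass, at -0.32, -0.33 and -0.45. Lyz2, the lysozyme of myeloid cells, rose from 10.46 ± 0.31 to 12.02 ± 0.08, and Clec7a, a receptor for beta-glucans, rose from 7.10 ± 0.29 to 8.38 ± 0.03 (limma adjusted p = 0.00209 and 0.00282). Lyz2 and its near-identical copy Lyz1 (1.36 ± 0.09, limma adjusted p = 0.000927) can share probe signal, so which of them changed is uncertain. Cd14, the lipopolysaccharide co-receptor, fell from 8.68 ± 0.12 to 7.65 ± 0.08 (limma adjusted p = 0.00181). Other genes with the highest differences were Mmp12 (2.27 ± 0.32), galectin-3 gene Lgals3 (1.74 ± 0.18), the fatty acid-binding protein gene Fabp5 (1.74 ± 0.22), the scavenger receptor gene Cd163l1 (1.65 ± 0.24), Kbtbd8 (1.38 ± 0.27), Hpcal4 (1.36 ± 0.13) and the potassium channel gene Kcnk2 (1.34 ± 0.16). Their limma adjusted p were 0.00884, 0.00282, 0.00579, 0.0104, 0.0269, 0.00194 and 0.00505. Calls lost on leaving out 1 array, with a limma adjusted p above 0.05, were those of Cd163l1 (without old 3, up to 0.0506) and Kbtbd8 (on leaving out any array except young 2, up to 0.117). With the mean of a gene's probe sets, the difference was 0.81 for Kbtbd8, past the threshold.

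The complement, interferon-stimulated and MHC lists passed upward by camera at a preset correlation, with 3, 2 and 1 members that passed singly. Of 19 complement genes, 3 rose and 0 fell (3 rising and 1 falling when adjusted over the list alone), namely the C3a receptor gene C3ar1 (1.37 ± 0.17), the integrin gene Itgb2 (0.77 ± 0.12) and Masp1 (0.43 ± 0.10). Their adjusted p in limma were 0.00521, 0.0124 and 0.0476. The complement median was 0.16 (camera adjusted p = 0.0229, and adjusted p = 0.520 with an estimated correlation). Of 31 interferon-stimulated genes, Trim30a (1.10 ± 0.24) and Oas1a (0.96 ± 0.19) rose and 0 fell (2 rising and 0 falling when adjusted over the list alone). In limma, the adjusted p were 0.0374 and 0.0278. The interferon-stimulated median was 0.23 (camera adjusted p = 0.00577, and adjusted p = 0.738 with an estimated correlation). Of 16 MHC class I and II genes, H2-Ab1 rose by 0.56 (limma adjusted p = 0.0303) and 0 fell (6 rising and 0 falling when adjusted over the list alone). The MHC median was 0.27 (camera adjusted p = 0.0134, and adjusted p = 0.306 with an estimated correlation). Of 16 T and NK cell genes, the T cell receptor component genes Cd3g (1.41 ± 0.10) and Cd3d (0.44 ± 0.10) and the chemokine gene Ccl5 (1.00 ± 0.12) rose and 0 fell (4 rising and 0 falling when adjusted over the list alone). The limma adjusted p were 0.000985, 0.0467 and 0.00498. Cd3g was dim in both ages, at 3.94 ± 0.08 and 5.35 ± 0.17, where the median of all probe sets was 6.28. The T and NK cell list did not pass (camera adjusted p = 0.105), and its camera adjusted p was 0.0141 without young replicate 1 and 0.0468 without old replicate 3. It was 0.0413 with the mean of a gene's probe sets. The list of 33 inflammatory cytokines and chemokines had 3 that rose, including Cxcl13 and Ccl12 (1.27 ± 0.18), and 1 that fell, the inhibitor of NF-kappaB gene Nfkbia (-0.58 ± 0.09). Limma gave adjusted p of 0.00822 and 0.0115 for the latter pair. That list had 4 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.622, fry adjusted p = 0.0164). Of 15 B and plasma cell genes, Blk rose by 0.59 (limma adjusted p = 0.0273) and 0 fell (1 rising and 0 falling when adjusted over the list alone, camera adjusted p = 0.650). The camera adjusted p was 0.0841 and 0.0531 for complement without young replicate 1 and without old replicate 2. It was 0.146, 0.063 and 0.101 for the interferon list without young replicate 1, young replicate 3 and old replicate 3, and 0.0606 for the MHC list without young replicate 1. Over probe sets above the median signal it was 0.0518 for complement and 0.0514 for the interferon list. By fry the adjusted p were 0.0699 and 0.267. With array weights the complement median was 0.10 (camera adjusted p = 0.0862), and without young replicate 2 the interferon median was 0.41. With an intensity trend and robust variance Masp1 (limma adjusted p = 0.0525) and Cd3d did not pass. Masp1 had 0.0505 with cyclic loess, and Cd3d had 0.0602 with array weights, as limma adjusted p. With 1 array left out, the limma adjusted p exceeded 0.05 for Itgb2 (without old 3, up to 0.0609), Masp1 (on leaving out any array except old 1, up to 0.169) and Trim30a (on leaving out any array except young 2, up to 0.141). Leaving out single arrays raised the limma adjusted p above 0.05 for Oas1a (on leaving out any array except young 2 and old 2, up to 0.118), H2-Ab1 (on leaving out any array except old 3, up to 0.102) and Cd3d (on leaving out any array, up to 0.144). In fits without 1 array, the limma adjusted p rose above 0.05 for Nfkbia (without young 3, up to 0.0554) and Blk (on leaving out any array except young 2 and old 1, up to 0.119). For the mean of all probe sets of a gene, the difference was 0.15 for Masp1 (adjusted p = 0.255) and 0.24 for H2-Ab1 (adjusted p = 0.0938), which did not pass.

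Lists for the cell types and potassium recycling of the lateral wall held 92 different genes, of which 8 passed, against 870 of all 18193 genes by the same threshold. At an unadjusted p under 0.05, 33 of the 92 passed, against 3762 of 18193, and these shares were not tested against each other. None of the 6 lists passed by camera, which tests for a shift in one direction. A mixed form of fry, which counts changes in either direction, gave the 6 lists adjusted p of 6.90e-05 to 0.0111. Lists of other tissues, such as skeletal muscle (0.00471), passed it too, so it does not set the lateral wall apart. Of 16 strial marginal cell genes, 1 rose and 0 fell (1 rising and 0 falling when adjusted over the list alone, camera adjusted p = 0.116), and the 1 was Stac (0.46 ± 0.09, limma adjusted p = 0.0257). Of 19 intermediate cell genes, the neural crest factor gene Sox10 rose by 0.38 and the endothelin receptor gene Ednrb fell by 0.36 (limma adjusted p = 0.0382 and 0.0443), with 4 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.155). Of 14 basal cell and tight junction genes, Sox8 (0.56 ± 0.13) and Marveld3 (0.46 ± 0.10) rose (limma adjusted p = 0.0469 and 0.0378), with 5 rising and 0 falling when adjusted over the list alone (camera adjusted p = 0.0748). Of 19 spiral ligament fibrocyte genes, the water channel gene Aqp1 fell from 10.52 ± 0.05 to 9.64 ± 0.17 (limma adjusted p = 0.00350) and 0 rose (0 rising and 1 falling when adjusted over the list alone, camera adjusted p = 0.0626). Of 14 spindle and root cell genes, Kcnk2 and the water channel gene Aqp4 (0.94 ± 0.20, limma adjusted p = 0.0397) rose, with 3 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.142). By their brightest probe sets, none of 21 genes for potassium recycling and gap junctions passed, though a dimmer probe set of the member Slc12a2 did. The list had 2 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.936). Kcnj16 and Kcnma1 had the smallest p in it, with differences of 0.43 ± 0.10 and 0.69 ± 0.18 (limma adjusted p = 0.0515 and 0.0673). Kcnj16 passed in 7 of 14 alternative settings and Kcnma1 in 4, with the lowest adjusted p, 0.0135 and 0.0228, under array weights. The mean of the probe sets of Kcnma1 had a difference of 0.12. The camera adjusted p of the basal cell list was 0.0435 without young replicate 2, and that of the fibrocyte list was 0.00941 without old replicate 2 and 0.0384 without old replicate 3. With the mean of a gene's probe sets these lists had camera adjusted p of 0.0242 and 0.0121, and the fibrocyte median was -0.07 against -0.03. The spindle and root cell list had an adjusted p of 0.0391 by fry for movement one way. Calls lost on leaving out 1 array, with a limma adjusted p above 0.05, were those of Stac (on leaving out any array except young 2 and old 2, up to 0.0906), Sox10 (on leaving out any array except young 2, up to 0.147) and Ednrb (on leaving out any array, up to 0.191). With 1 array left out, the limma adjusted p exceeded 0.05 for Sox8 (on leaving out any array except young 2, up to 0.179), Marveld3 (on leaving out any array except young 2 and old 2, up to 0.161) and Aqp4 (on leaving out any array, up to 0.107). Averaged over a gene's probe sets, the difference was -0.59 for Ednrb, past the threshold. It was 0.17 for Sox10 (adjusted p = 0.174), 0.21 for Marveld3 (adjusted p = 0.186) and 0.50 for Aqp4 (adjusted p = 0.0720), which did not pass.

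Genes central to the endocochlear potential and to hereditary deafness were followed whatever their result. Kcnj10 had a difference of -0.02 ± 0.09, the marginal cell potassium channel gene Kcnq1 of 0.03 ± 0.11, the gap junction gene Gjb2 of 0.14 ± 0.08, the pendrin gene Slc26a4 of 0.07 ± 0.08, the cochlin gene Coch of -0.07 ± 0.07, the otospiralin gene Otos of -0.19 ± 0.08 and the transcription factor gene Pou3f4 of 0.04 ± 0.08. Their limma adjusted p were 0.932, 0.935, 0.373, 0.747, 0.709, 0.215 and 0.873. That of Otos was 0.0284 with an intensity trend and robust variance. The brightest probe set of Slc12a2, the sodium-potassium-chloride cotransporter gene, had a difference of 0.01 ± 0.07 (limma adjusted p = 0.980), whereas another of its probe sets fell by 0.46 (limma adjusted p = 0.0292). The remaining probe set of Slc12a2 had a difference of -0.18 (limma adjusted p = 0.313). Coch, Otos and Slc12a2 had young means of 14.44, 14.19 and 13.95, where the highest signal of an array was 14.72 to 14.76. Whether differences are compressed at such signals was not examined.

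Markers of vessels, nerve and neighbouring tissues were examined because the dissection could hold them. Of 18 pericyte and smooth muscle genes, the contractile genes Tagln (-1.23 ± 0.14) and Acta2 (-0.74 ± 0.10) fell and 0 rose (1 rising and 2 falling when adjusted over the list alone). Their adjusted p in limma were 0.00393 and 0.00612. The median was -0.10 (camera adjusted p = 0.0265, and adjusted p = 0.520 with an estimated correlation), and the camera adjusted p was 0.088 without young replicate 1. The median was -0.03 there and -0.22 without young replicate 2, and fry gave an adjusted p of 0.166. Of 25 endothelial genes, Sox18 rose by 0.62 (limma adjusted p = 0.0315) and 0 fell (1 rising and 0 falling when adjusted over the list alone, camera adjusted p = 0.932). Of 21 hair cell and organ of Corti genes, Otog rose by 1.10 (limma adjusted p = 0.0470) and 0 fell (1 rising and 1 falling when adjusted over the list alone, camera adjusted p = 0.388). Of 19 neuronal genes, the microtubule-associated protein gene Map1b fell from 10.40 ± 0.08 to 9.61 ± 0.19 (limma adjusted p = 0.00699) and 0 rose (0 rising and 1 falling when adjusted over the list alone, camera adjusted p = 0.116). Of 16 Schwann cell and myelin genes, Ncmap (-0.59 ± 0.11) and Pmp22 (-0.51 ± 0.10) fell (limma adjusted p = 0.0257 and 0.0265), with 1 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.330). Casq1 was the 1 of 23 skeletal muscle genes that fell (-0.87 ± 0.11, limma adjusted p = 0.00544), with 0 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.694). Bpifb1 was the 1 of 16 respiratory and middle ear epithelium genes that rose (1.21 ± 0.21, limma adjusted p = 0.0186), with 1 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.942). The camera adjusted p was 0.0498 for the hair cell list without old replicate 1 and 0.0154 for the neuronal list without old replicate 2. The limma adjusted p of Otog was 0.0503 after quantile normalization again and 0.0529 with cyclic loess. Leaving out single arrays raised the limma adjusted p above 0.05 for Sox18 (on leaving out any array except young 1 and young 2, up to 0.109), Otog (on leaving out any array except old 1, up to 0.161) and Ncmap (on leaving out any array except young 2 and old 2, up to 0.114). In fits without 1 array, the limma adjusted p rose above 0.05 for Pmp22 (on leaving out any array except young 2 and young 3, up to 0.120) and Bpifb1 (without young 1 or young 3 or old 1, up to 0.0651). With the mean of a gene's probe sets, the difference was -0.49 for Map1b, past the threshold. It was -0.25 for Acta2 (adjusted p = 0.0753), which did not pass.

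A few cell division genes fell, and signalling genes moved both ways. Of 39 cell cycle and mitosis genes, 4 fell, 0 rose and 35 did not pass (1 rising and 9 falling when adjusted over the list alone). The cell cycle median was -0.06 (camera adjusted p = 0.00128, and adjusted p = 0.255 with an estimated correlation). The 4 were Kif23 (-1.61 ± 0.16), Birc5 (-1.07 ± 0.09), the proliferation marker gene Mki67 (-0.88 ± 0.16) and Nusap1 (-0.36 ± 0.08). In limma, the adjusted p were 0.00232, 0.00114, 0.0213 and 0.0442. Birc5, Mki67 and Nusap1 were dim, with means of 5.97, 5.34 and 5.95 in young and 4.90, 4.46 and 5.59 in old tissue. The median of all probe sets was 6.28. When only probe sets above the median signal were tested, the median of this list was 0.02 and its camera adjusted p 0.397. The median lay between -0.12 and -0.02 with 1 array left out and was -0.10 with array weights. Nusap1 had a limma adjusted p of 0.0633 with an intensity trend and robust variance. Of 36 TGF-beta and BMP genes, Id4 (0.70 ± 0.11) and Smad5 (0.35 ± 0.08) rose and Ccn2 (-1.04 ± 0.13) and Id1 (-0.87 ± 0.11) fell. The limma adjusted p were 0.0143, 0.0403, 0.00589 and 0.00509. Another probe set of Smad5 fell by 0.35 (limma adjusted p = 0.0476). That list had 3 rising and 4 falling when adjusted over the list alone (camera adjusted p = 0.101, and 0.0335 without old replicate 2). Of 37 Wnt and Notch genes, 2 rose, Fzd8 (0.74 ± 0.15) and the ligand gene Jag1 (0.57 ± 0.12), and 3 fell, including the receptor gene Notch4 (-0.58 ± 0.13) and Sfrp4 (-0.50 ± 0.10). Their limma adjusted p were 0.0286, 0.0339, 0.0391 and 0.0284, and the list had 2 rising and 3 falling when adjusted over the list alone (camera adjusted p = 0.565). Ankrd37 was the 1 of 24 angiogenesis and hypoxia genes that rose (0.67 ± 0.11, limma adjusted p = 0.0156), with 1 rising and 0 falling when adjusted over the list alone (camera adjusted p = 0.968). Insig1 was the 1 of 24 cholesterol and fatty acid synthesis genes that fell (-0.47 ± 0.10, limma adjusted p = 0.0417), with 0 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.388). Calls lost on leaving out 1 array, with a limma adjusted p above 0.05, were those of Mki67 (on leaving out any array except young 2 and old 1, up to 0.0912), Nusap1 (on leaving out any array, up to 0.149) and Id4 (without old 3, up to 0.0669). With 1 array left out, the limma adjusted p exceeded 0.05 for Smad5 (on leaving out any array except young 2, up to 0.163), Fzd8 (on leaving out any array except young 2, up to 0.116) and Jag1 (on leaving out any array except young 2 and old 1, up to 0.130). Leaving out single arrays raised the limma adjusted p above 0.05 for Notch4 (on leaving out any array except young 2, up to 0.120), Sfrp4 (on leaving out any array except young 2 and young 3, up to 0.119) and Ankrd37 (on leaving out any array except young 2 and old 2, up to 0.0769). In fits without 1 array, the limma adjusted p rose above 0.05 for Insig1 (on leaving out any array, up to 0.127). For the mean of all probe sets of a gene, the difference was -0.62 for Kif23, past the threshold. It was -0.29 for Nusap1 (adjusted p = 0.0706), 0.42 for Id4 (adjusted p = 0.0719), 0.09 for Smad5 (adjusted p = 0.591), 0.43 for Fzd8 (adjusted p = 0.0682), 0.13 for Jag1 (adjusted p = 0.428) and -0.25 for Notch4 (adjusted p = 0.153), which did not pass.

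No gene for the respiratory chain, the ribosome or microRNA processing passed by its brightest probe set. The 64 mitochondrial respiratory chain genes had a median of 0.04, with 0 rising and 0 falling when adjusted over the list alone (camera adjusted p = 0.259). The smallest p among them were those of Ndufb4 (0.43 ± 0.15) and Atp5g1 (0.19 ± 0.08). Limma gave adjusted p of 0.147 and 0.257. Ndufb4 passed in 2 of 13 alternative settings, at 0.0299 with array weights. The 39 ribosomal protein genes had a median of 0.05, with 0 rising and 0 falling when adjusted over the list alone (camera adjusted p = 0.330). Rpl12 (0.24 ± 0.08) and Rps6 (0.16 ± 0.08) came first. Their adjusted p in limma were 0.130 and 0.30, and that of Rpl12 was 0.0491 with array weights. The 22 microRNA processing genes had a median of 0.10, with 0 rising and 0 falling when adjusted over the list alone (camera adjusted p = 0.415). The Argonaute gene Ago3 (-0.38 ± 0.10) and the terminal uridylyltransferase gene Tut4 (-0.28 ± 0.08) had the smallest p. In limma, the adjusted p were 0.0752 and 0.0886. At an unadjusted p under 0.05, 2 of the mitochondrial, 1 of the ribosomal and 6 of the microRNA processing genes passed. Of 10 sex-linked genes, Kdm5c rose by 0.44 (limma adjusted p = 0.0179) and 0 fell (1 rising and 0 falling when adjusted over the list alone, camera adjusted p = 0.995). The limma adjusted p of Kdm5c exceeded 0.05 without young 3 or old 2 or old 3, up to 0.0982. Averaged over a gene's probe sets, the difference was 0.09 for Kdm5c (adjusted p = 0.587), which did not pass.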

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

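The planned setting without young replicate 2 was also listed as an added one, chosen after its Xist value was seen, and both are the same fit. Under quantile normalization again, median centring, cyclic loess, the filter on dim probe sets, and the intensity trend with robust variance, the count of called probe sets stayed between 2239 and 2676 and that of genes between 906 and 1275, against 2119 and 885. With array weights 4480 probe sets and 1999 genes were called, 1273 of the genes higher and 726 lower in old tissue, and the cause was not tested. The stricter adjusted p of 0.01 left 436 probe sets, and 213 with at least 2-fold change, by its construction. Leaving out 1 array gave 515 to 3393 probe sets, 247 to 1635 genes, 227 to 469 probe sets with at least 2-fold change, and 11 to 18 lists. The lowest counts of probe sets and genes came without old replicate 3. The highest came without young replicate 2, and there the share of called genes that were higher in old tissue was 69.1%, against 51.3% with all arrays. That share was 40.6% without young replicate 1, 37.8% without young replicate 3 and 50.8% without old replicate 1. It was 33.8% without old replicate 2 and 35.6% without old replicate 3, so the balance of directions depended on single arrays. Fewer samples leave less power, but the rise without young replicate 2 was not tested for a cause. That array also differed in its sex-linked signals, with Xist at 6.06 against 11.95 to 12.65 on the others. All 15 called lists kept their calls under the 3 normalizations and the intensity trend, and 11 under the filter, which left 14 of them testable. With an estimated correlation 0 of 42 lists were called by camera at an adjusted p of 0.05, with adjusted p of 0.255 to 0.738 for the 15 lists, while 6 passed at an unadjusted p under 0.05 and fry called 11, of which 9 were among the 15. Under the camera settings without 1 array, 10 of the 15 lists kept their calls throughout. Of the 95 named genes that were called, 45 kept their calls in all 6 settings without 1 array and 50 lost them in at least 1. The mean of a gene's probe sets in place of the brightest lost 15 of the 95 calls. None of the 95 changed sign under any alternative, and no called list changed its camera direction, but the cell cycle median was 0.02 under the filter, against -0.06. The median, the mean and the camera direction differed in sign, or the median was 0.00, for the endothelial, B and plasma cell, antioxidant, skeletal muscle, respiratory epithelium, angiogenesis and sex-linked lists, none of which was called.

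Whether the replicate numbers mark a shared batch or pairing is not settled by these values. On the second principal component, with 18.7% of the variance, young replicate 1 (22.3) and old replicate 1 (19.3) stood apart from the other arrays (-24.1 to -0.96). The control probe set CreX-3 read 12.81 and 12.82 on young and old replicate 1 and 13.10 to 13.54 on the others. Deviations from the age means correlated at 0.137, 0.0753 and 0.00782 for the numbers 1, 2 and 3, so 1 of 3 pairs exceeded 0.1, and 4 of the 6 arrays correlated best with their own number. With the replicate block, 1932 probe sets and 870 genes were called, 343 probe sets with at least 2-fold change and 16 lists, and 1605 of the 1932 probe sets were also called without it. The block ended the calls of 11 of the 95 named genes and gave 1 to Kcnma1, with an adjusted p of 0.0342. It gave the matrix degradation list an adjusted p of 0.0377 by camera and changed no other list call. Depth on arrays is limited by signal over background, which was not examined, so low signals such as that of Cd3g have an unknown floor.

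The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2119 probe sets, 885 genes and 337 probe sets with at least 2-fold change, each in 1 of 10 splits, and the highest of the others was 0 by limma. At an unadjusted p under 0.05 the real split had 8655 probe sets and the highest of the others 3662. For the fixed lists the real split called 15 with camera, and so did 1 other split, young replicates 1 and 3 with old replicate 2, so 2 of 10 splits gave as many. The 9 other splits, which mix the ages, called 2 to 15 lists, though limma called 0 probe sets in each. Each of these splits still set unequal numbers of young and old arrays against each other, so part of an age difference remained in it. Their list calls thus cannot show how many would arise without an age difference. With an estimated correlation, camera called 0 of 42 lists. A call at the preset correlation alone is therefore not taken to show a difference between the ages.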

Other observations

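The tests on zinc finger genes, on rhythmic output genes, on the order of bone and marrow values and on type IV collagens were chosen after the results they weigh were seen. Hspa8, Prl, Gh and the type IV collagens were also singled out after their values were seen. The tests on glucocorticoid receptor targets and on pituitary genes were chosen after the main results were seen, but before the values of the genes they use were seen.

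Several glucocorticoid receptor targets outside the fixed lists were lower in old tissue. Of 12 chosen genes 10 were measured, and 5 fell, 0 rose and 5 did not pass. Klf9, a transcription factor gene induced by glucocorticoids, fell from 13.45 ± 0.12 to 12.64 ± 0.08 (limma adjusted p = 0.00372). Errfi1, Pik3r1, Usp2 and Lpin1 had differences of -0.64 ± 0.09, -0.73 ± 0.15, -0.69 ± 0.09 and -0.37 ± 0.08 (limma adjusted p = 0.00699, 0.0346, 0.00634 and 0.0431). Zinc finger genes with numbered Zfp symbols leaned the other way, with 242 of 336 above 0 and 10 that rose against 6 that fell. The mean over these genes differed by 0.16 with a standard error of 0.07 over arrays, camera gave p = 0.354 with an estimated correlation, and young replicate 2, at 7.69, lay among the old arrays. The type IV collagens of basement membranes, which are members of the collagen list, were lower for Col4a3 (-0.86 ± 0.18), Col4a4 (-0.60 ± 0.13) and Col4a1 (-0.60 ± 0.14), with limma adjusted p of 0.0323, 0.0374 and 0.0470. Col4a2, Col4a5 and Col4a6 did not pass, at -0.48 ± 0.15, -0.14 ± 0.12 and -0.08 ± 0.12 (limma adjusted p = 0.106, 0.609 and 0.788). Called probe sets that were not the brightest of their gene were lower in old tissue in 573 of 817 cases, against 424 of 870 for the brightest ones (Fisher's exact test, 2-sided p = 3.39e-19, over probe sets, which are not independent). One probe set of the chaperone gene Hspa8 rose by 2.10 (limma adjusted p = 0.00110), while its brightest probe set had a difference of 0.01.

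Immediate early and glucocorticoid response genes were lower in old tissue. A general loss of short-lived RNA in the old samples would lower zinc finger transcripts too. Their median difference was 0.117, where a value below -0.1, a bound set after the results were seen, would have gone with such a loss. Over arrays the 95% interval of the mean difference was -0.09 to 0.41 (Welch). Zinc finger transcripts were thus not seen to fall. The interval includes 0 and starts close to the bound, so it cannot decide whether such a loss took part. Stronger glucocorticoid signalling in the young samples at collection, for example from handling, is a candidate explanation for the glucocorticoid-induced genes. The median difference of the 10 targets outside the lists was -0.392, and camera gave p = 0.0117 with an estimated correlation. Of 10000 random lists matched on signal 0 were as low, though these lists do not allow for correlated genes. The targets do not include immediate early genes such as Egr3 and Fos, whose fall was not tested this way. A different time of day at dissection cannot be told apart from stronger glucocorticoid signalling. The 5 rhythmic output genes had a median of -0.03 but went both ways. Dbp was at -0.50, Tef at -0.12, Nr1d2 at -0.03, Hlf at 0.11 and Per3 at 0.14. They are members of the clock list, of which 7 of 19 measured genes fell and 0 rose. Times on both sides of their peak would also give a median near 0. The 3′ excess of the Gapdh control probe sets was 1.36 ± 0.10 in old against 1.18 ± 0.10 in young arrays (exact 2-sided permutation p = 0.1, the smallest possible). It goes the way of RNA loss, so RNA loss stays open, as does age itself, which was not tested separately.

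Several bone and marrow transcripts were lower in old tissue. Less bone with its marrow carried over in the old dissections may account for this. The 3 arrays of an age had the same order in the mean of 12 bone genes other than collagens and of the 17 marrow myeloid genes. This held in 2 of 2 ages, which chance gives in 1 of 36. The erythroid list had another order in each age, with means of 6.25, 5.97 and 6.32 in young and 5.90, 5.81 and 5.82 in old arrays. The marrow myeloid means were 6.54, 6.80 and 6.90 in young and 5.96, 6.14 and 5.80 in old arrays. Bone and marrow myeloid signals thus varied together within an age, but erythroid signals did not follow them. These orders cannot show why the ages differ. Of 12 osteoclast genes, Atp6v0d2 and Acp5 went the other way, at 1.73 and 0.90, and 0 fell. For the type IV collagens, with a median of -0.54 against 0.00 for the endothelial list, it cannot be told apart: the outcome set against it, a fall of Col4a3 and Col4a4, was met (limma adjusted p = 0.0323 and 0.0374) but repeats the observation that prompted the test, and the endothelial genes went both ways, 13 above 0 and 12 below. Col1a2, the collagen with the lowest difference, is also a bone gene, and the fall of other fibrillar chains was not tested against this carry-over. Its signals in old arrays, 8.87, 9.73 and 8.67, had the order of the means of the bone genes other than collagens, 7.09, 7.43 and 6.85. In young arrays its signals were 12.27, 11.45 and 11.62, against bone means of 7.80, 8.02 and 8.14, so there the order differed. These orders do not decide whether carry-over accounts for Col1a2. Lower bone turnover with age was not tested and stays open.

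Prl and Gh, hormone genes of the pituitary gland, had signals that varied between arrays, and their background was not examined. Prl was 6.81, 4.63 and 7.45 in young and 10.84, 9.15 and 7.69 in old arrays, and Gh was 8.19, 6.33 and 7.25 against 9.36, 8.86 and 7.96 (limma adjusted p = 0.0968 and 0.122). Pituitary tissue carried over in the dissection was tested with 15 other pituitary genes, of which 14 were measured. Between the arrays with the highest and the lowest Prl, old replicate 1 and young replicate 2, their median difference was 0.20. This was at the bound set against carry-over (under 0.20) and below the 0.5 set for it. Of the 14 genes 10 were above 0, with 3 at 0.5 or more (Cga 0.82, Tbx19 0.61 and Fshb 0.51), Pomc at 0.48, and Chgb, the lowest, at -0.33. The contrast sets 1 array against 1 array, and these also differ in age and in Xist signal (12.27 against 6.06). Because 12 of the 14 had signals under the median of all probe sets, 6.28, on all 6 arrays, carry-over and another source cannot be told apart, and age was not tested separately.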
